A study of Homo sapiens with 9 samples.

How the data were processed

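Gene expression was measured by RNA sequencing in tumours that A375 cells formed in nude mice. A375 is an established human melanoma line with a BRAF mutation. The cells carried a doxycycline (Dox) inducible construct for RNF4, a ubiquitin ligase that targets SUMO-modified proteins, or for a RING mutant of RNF4 without catalytic activity. Dox was given in drinking water from day 3 and tumours were taken at day 30. Each library came from 2 pooled tumours, and 3 groups of 3 libraries were deposited: RNF4 without Dox, RNF4 with Dox and RING mutant with Dox. The series text names GFP tumours as the control, whereas the sample titles describe the control libraries as RNF4 without Dox. Samples were grouped by their titles. Libraries were strand-specific and poly(A)-selected, made from 800 ng of RNA, combined in 1 tube and sequenced as single 50-base reads.

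The deposited tables give raw counts per gene for 57820 gene identifiers, and the same counts stand in each of the 3 tables. Per the labels, reads were aligned with TopHat2 2.0.13 to GRCh38 and counted with HTSeq 0.6.0, and DESeq2 1.10.1 was used. The tables also carry tagwise and trended dispersion columns of the kind edgeR writes, so which of the authors' tools gave the deposited fold changes is open. The authors give a log2 fold change and an adjusted p value for each comparison, and lists of genes higher or lower. They tested 16002 genes, which are the genes at 1 CPM or more in at least 3 libraries. The authors' normalised values, 9 columns per table, were not used. Library columns are numbered T1 to T14 and sample titles carry other numbers, so columns could be assigned to groups but not to single samples. Libraries are named here by column: T1, T4 and T12 for RNF4 without Dox, T2, T5 and T13 for RNF4 with Dox, T3, T6 and T14 for RING mutant with Dox.

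Symbols came from the gene identifier. Coordinates are GRCh38 from GENCODE 29, joined by identifier without its version, because the deposited tables hold no coordinates and name no annotation release. Of the identifiers, 52338 were found in GENCODE 29 and 29842 had the same version.

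Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr with the 3 groups, which left 18618, and scaled with TMM factors. A negative binomial quasi-likelihood model with 1 mean per group was fitted to all 9 libraries. Each of 3 contrasts, and any difference among the 3 groups, was tested with edgeR's two-sided quasi-likelihood F-test. An adjusted p (Benjamini-Hochberg) under 0.05 counted as a call. Normalised read counts are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries. Fold changes are log2 with a standard error derived from the test, the absolute log2 change over the square root of the F statistic. For genes with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio has an exact 95% interval from the binomial distribution. These bounds cover counting error only.

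A set of 36 gene lists, holding pathway genes and markers of host cells that a tumour in a mouse could contain, was fixed before the data were examined. The labels name only the human genome GRCh38 for alignment. Counts of host markers can thus come from mouse reads that align to human genes or from the tumour cells, which was not tested. The 35 lists with at least 5 measured members were tested with limma 3.58.1 (camera on log CPM with a prior count of 2, preset correlation 0.01), adjusted over the lists within a comparison. Camera was run again with the correlation estimated from the data. The mean log2 difference of a list is the difference of group means of log CPM averaged over its members. The method was tested on simulated data with 50 changed genes at each fold. At a 4-fold change 34, 32 and 30 of 50 were recovered in the 3 contrasts, at 2-fold 3, 3 and 5, and at 8-fold 42, 41 and 44, with 4, 4 and 14 false calls. This recovery does not carry over to the data, where RNF4, near 10-fold higher with RNF4 and Dox than without, was not called.

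The rule for naming genes was also fixed beforehand. In each comparison it takes RNF4, up to 8 genes each way and 2 members per list among genes past the adjusted threshold (there were 0), and, with fewer than 10 such genes, the 5 with the smallest unadjusted p in each direction. It adds the 2 members with the smallest unadjusted p of each list that is described, 7 genes tied to RNF4 or melanoma in earlier work, and up to 8 genes each way from the authors' lists by their adjusted p. Alternatives chosen at that point were RLE factors, no filter on low counts, a filter of 1 CPM in 3 libraries, a score of the host lists as covariate, only the 6 libraries compared, DESeq2 1.42.0, and leaving out each library in turn. Those chosen after seeing the data were edgeR's likelihood ratio test, limma voom with sample quality weights, offsets for GC content and transcript length, a block for runs of tumour numbers, and leaving out T1 and T2, T13 and T14, or T3 and T14. T3 and T14 were left out because their RNF4 counts are in doubt. Both comparisons against RNF4 without Dox share its 3 libraries, so the correlation of their fold changes was set beside 20 simulations of unchanged groups with shared controls, drawn without effects shared within runs.

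Depth ranged from 16416426 to 28934692 counts per library. Over all genes together, the chi-square per degree of freedom between pairs of libraries of 1 group ran from 19.2 to 504, where counting error alone gives about 1. Genes with high counts weigh most in that value, so it does not give the precision of single genes. A comparison of a single value between 3 and 3 libraries by permutation cannot go below an exact p of 0.1.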

Results

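Messenger RNA was profiled in 9 pools of A375 melanoma tumours, 3 with the RNF4 construct and no Dox, 3 with RNF4 and Dox, and 3 with the RING mutant and Dox. Total counts were 20159280, 28934692 and 23513224 in the RNF4 libraries without Dox (T1, T4, T12). They were 23492933, 21199826 and 22743326 with RNF4 and Dox (T2, T5, T13), and 16594911, 21271402 and 16416426 in the libraries labelled RING mutant (T3, T6, T14). Between 26070 and 29482 genes had counts in a library. Ribosomal protein genes took 17.4% of counts in T1 and 11.1% in T2, against 4.80% to 6.92% in the other 7 libraries. The first principal component carried 56.3% of the variance and set T1 and T2 apart from the rest.

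RNF4 (ENSG00000063978.11; GRCh38 by GENCODE 29, chromosome 4, 2462220 to 2625320, plus strand) is the gene that both constructs carry. Its normalised read count was 42.9 ± 9.32 CPM (SD, n = 3) without Dox and 416 ± 37.2 CPM with RNF4 and Dox. Every library of RNF4 with Dox lay at 8.87 to 10.6 times the mean without Dox. The libraries labelled RING mutant were split. T6 had 559 CPM, 13.05 times the mean without Dox, whereas T3 had 47.0 CPM and T14 had 63.5 CPM, 1.098 and 1.48 times that mean. Every statement below on the RING mutant group therefore concerns libraries by their label, and 2 of the 3 show RNF4 near its level without Dox.

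**Figure D1:**
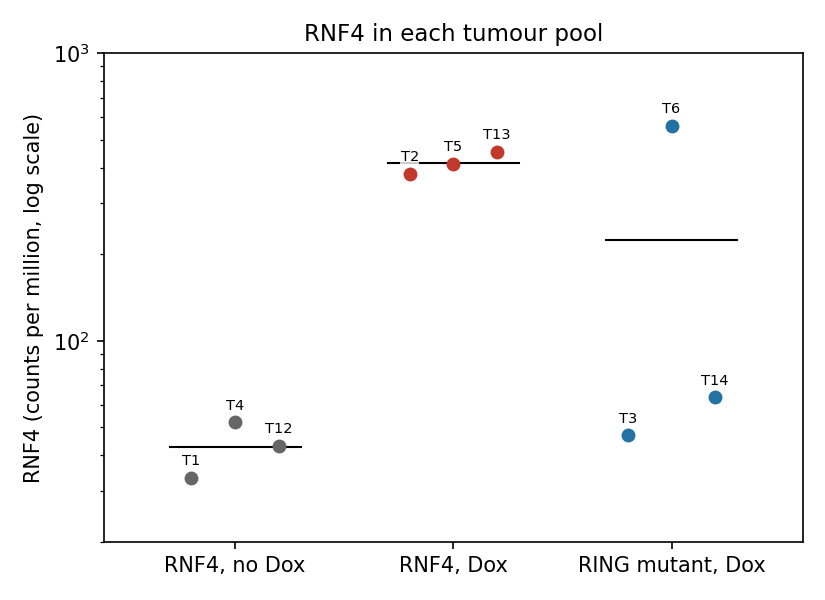
RNF4 in normalised read counts (CPM, log axis) for each tumour pool, grouped by construct and Dox; points are libraries and the line is the group mean of 3. The RNF4 libraries with Dox lie between 380 and 454 CPM, and of the libraries labelled RING mutant T6 lies at 559 while T3 and T14 lie at 47.0 and 63.5.

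The comparison of RNF4 with Dox against RNF4 without Dox asks which transcripts differ when Dox is given and the ligase is induced. No group received Dox without an RNF4 construct, so effects of Dox and of the ligase cannot be told apart here. UNC5C, a receptor for netrin, averaged 11.2 ± 2.67 CPM (SD, n = 3) with Dox and 0.599 ± 0.380 CPM without, and its antisense neighbour UNC5C-AS1 had 188 counts against 3, a ratio of 66.2 (95% interval 22.3 to 324). In the libraries labelled RING mutant UNC5C was at 5.10 CPM in T3, 4.24 in T6 and 0.170 in T14, so it was also raised in T3, where RNF4 was not. ITGA1, the alpha 1 subunit of a collagen-binding integrin, stood at 39.9 ± 8.82 CPM with Dox and 87.5 ± 12.6 CPM without. WNT7B, a Wnt ligand, stood at 1.95 ± 0.286 against 5.53 ± 1.57 CPM, and SYTL5, ST3GAL5 (which makes the ganglioside GM3) and LINC01239 were also lower in all 3 libraries with Dox. None of these differences passed an adjusted p of 0.05 in the edgeR fit.

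The fitted log2 changes were 3.28 ± 0.84 (SE) for RNF4, 4.14 ± 0.93 for UNC5C and 5.88 ± 1.24 for UNC5C-AS1. EFEMP1, an extracellular matrix protein, had 1.04 ± 0.33, and CAVIN2, a component of caveolae, had 2.03 ± 0.68. Among lower genes the values were -1.13 ± 0.22 for ITGA1, -1.50 ± 0.33 for WNT7B, -0.87 ± 0.19 for SYTL5, -1.18 ± 0.29 for LINC01239 and -0.88 ± 0.23 for ST3GAL5. UNC5C (chromosome 4, 95162504 to 95549206, minus strand) and UNC5C-AS1 (95549129 to 95552457, plus strand) overlap at the UNC5C promoter end. ITGA1 lies on chromosome 5 at 52787896 to 52959210. The authors' lists for this comparison hold 3 genes, all higher: UNC5C-AS1 (log2 change 5.89), UNC5C (4.17) and RNF4 (3.275), with the authors' adjusted p at 0.000342, 0.00292 and 0.0132.

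edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 18618 genes, with a smallest adjusted p of 0.99998. At an unadjusted p under 0.05 there were 111 genes, 25 higher and 86 lower, where chance alone would give 931. The smallest unadjusted p in that edgeR test was 0.000411, for ITGA1. DESeq2's Wald test called 3 genes (UNC5C and UNC5C-AS1 higher, ITGA1 lower) and returned no p for RNF4, edgeR's likelihood ratio test called UNC5C-AS1 alone, and limma voom called 0. Without a low-count filter the quasi-likelihood test called 3 (UNC5C, UNC5C-AS1 and RNF4). RNF4's spread in this fit takes in the split between T6 and the other libraries of its label. With only the 6 libraries compared, its edgeR adjusted p was 0.0878. Groups did not overlap for 432 genes, 2.32% of those tested, where exchangeable libraries give 10%. The 931 and the 10% assume libraries without shared effects. Deviations from group means correlated across groups within runs of column numbers (T1 to T3, T4 to T6, T12 to T14), at 0.675 for T1 and T2. A shortfall therefore does not show less separation than chance.

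8 of 35 gene lists passed camera's preset test, and none held with an estimated correlation. Genes of the ATF4 amino acid response rose, 29 of 31 members above 0 with a mean log2 difference of 0.24 (adjusted p = 4.01e-09 by limma's camera, adjusted p = 0.931 with an estimated correlation). PCK2, a mitochondrial enzyme of phosphoenolpyruvate synthesis, had 0.36 ± 0.16, and ALDH1L2, a mitochondrial folate enzyme, had 0.43 ± 0.22. The hypoxia list rose by a mean of 0.14 with 25 of 29 members above 0 (camera adjusted p = 0.00135), with the peptide hormone gene ADM at 0.53 ± 0.27 and the glucose transporter SLC2A3 at 0.34 ± 0.26. That rise rested on T2 and T5: T13 stood at -0.11 on the list, below T4 (0.11) and T12 (0.13) without Dox. The call was lost without T1 (mean 0.060), T2 (0.096) or T5 (0.034), whereas the ATF4 call held with each library left out. The ATF4 list stood at 0.25, 0.27 and -0.03 in T2, T5 and T13, and at -0.12, 0.12 and -0.21 in T1, T4 and T12. It was thus higher with Dox in T2 than in T1, in T5 than in T4 and in T13 than in T12, the libraries with neighbouring column numbers, although T13 lay below T4. This pairing was chosen after seeing the data and does not set the ATF4 list apart. The heat shock list was also higher with Dox in each pair, at 0.13, 0.14 and 0.02 in T2, T5 and T13 against 0.0052, 0.12 and -0.17 in T1, T4 and T12. ALDH1L2 fell to 0.28 without T1, ADM to 0.22 without T5 and SLC2A3 to 0.12 without T5. Smaller mean rises were called for G2/M genes (0.10, camera adjusted p = 0.0125), glycolysis (0.13, 0.0169), heat shock genes (0.11, 0.0250) and MYC targets (0.08, 0.0268). Histone genes fell by a mean of -0.24 with 9 of 11 members below 0 (camera adjusted p = 0.0268). For the hypoxia, G2/M, glycolysis, heat shock, MYC target and histone lists the adjusted p was 0.938 with an estimated correlation.

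Members of these smaller lists had modest values. CDC20 and CKS2 of the G2/M list had 0.24 ± 0.24 and -0.78 ± 0.88, PFKM and SLC16A1 of glycolysis 0.19 ± 0.25 and 0.15 ± 0.21, and DNAJB1 and HSPD1 of the heat shock list 0.27 ± 0.26 and 0.20 ± 0.27. PA2G4 and IPO4 of the MYC targets had 0.27 ± 0.24 and -0.32 ± 0.32, and the histone genes H4C3 and H4C8 had -1.05 ± 0.60 and -0.63 ± 0.38. Single libraries carried many of these values: without T1 CKS2 was 1.27, PFKM -0.026, PA2G4 0.14 and H4C3 -0.081, without T2 SLC16A1 was -0.0086 and HSPD1 0.0098, and without T12 CDC20 was 0.14, DNAJB1 0.16, IPO4 -0.14 and H4C8 -0.29. Skeletal muscle markers, which the surrounding host tissue can bring, rose by a mean of 1.24 with 16 of 16 members above 0 (camera adjusted p = 2.29e-06, adjusted p = 0.938 with an estimated correlation). They were uneven within the group, at 0.95 in T2, -1.99 in T5 and 1.84 in T13 relative to the mean of all libraries. MYH2 and MYH4 had 1.78 ± 1.06 and 2.27 ± 1.38, and 0.78 and 0.64 without T13. The muscle call was lost without T13 (mean 0.46). The G2/M mean turned to -0.033 without T2 and -0.031 without T12, and its call was lost without T1 (0.18). The glycolysis mean turned to -0.021 without T1, and its call was lost without T12 (0.16) or T5 (0.015). The heat shock call was lost without T1 (0.19), T12 (0.062), T2 (0.13) or T5 (0.14), and the MYC target call without T1 (0.053), T12 (0.039), T2 (0.074) or T5 (0.064). The histone call was lost without T1 (-0.10), T12 (-0.24), T5 (-0.21) or T13 (-0.12). By member, 0 genes passed adjusted over the list alone.

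**Figure D2:**
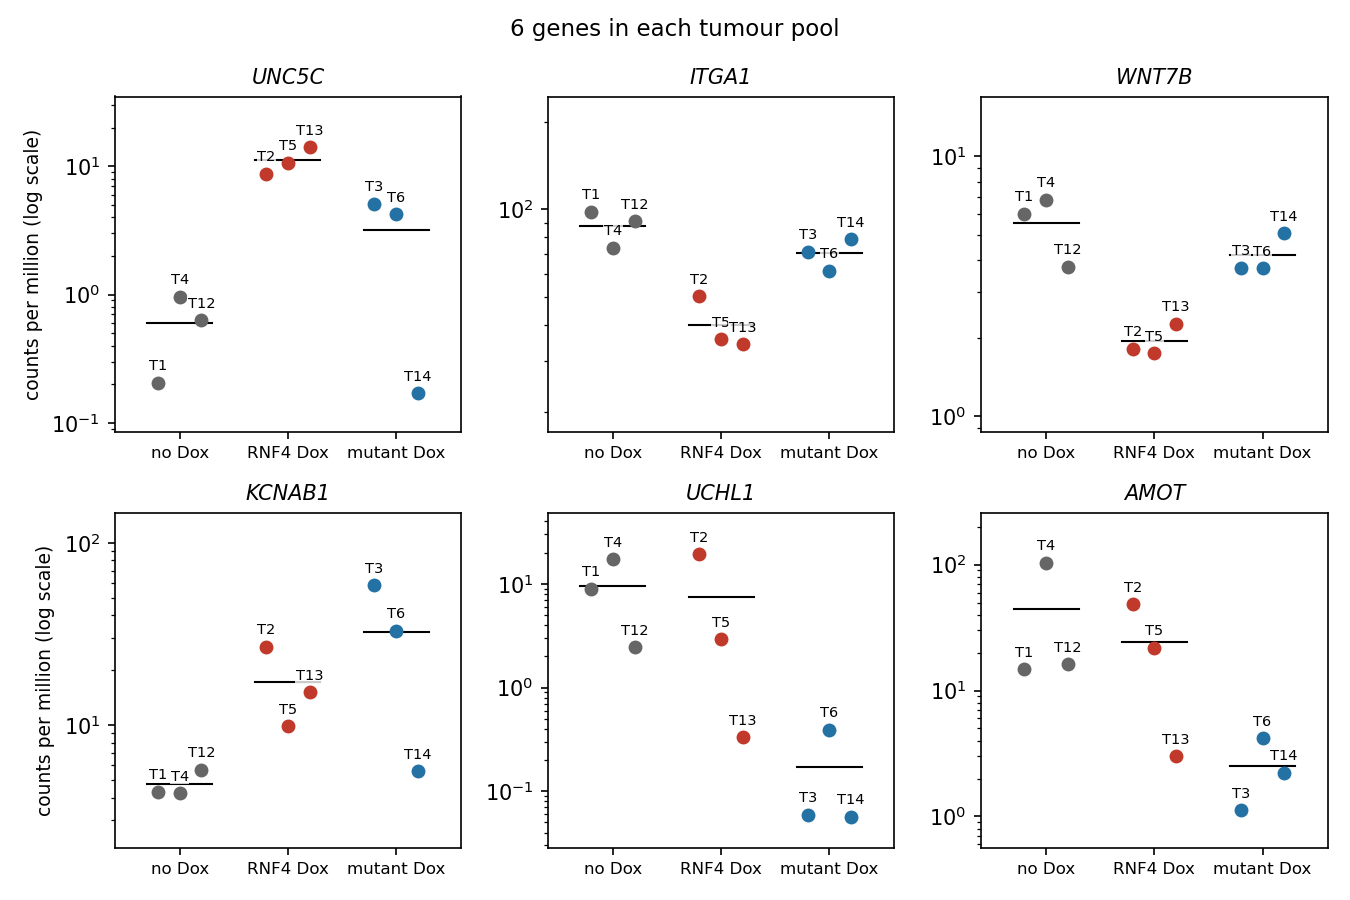
Normalised read counts (CPM, log axis) of 6 genes for each tumour pool, grouped by construct and Dox; points are libraries and lines are group means of 3. UNC5C is at 8.80 to 14.1 CPM in RNF4 libraries with Dox and at 5.10, 4.24 and 0.170 in T3, T6 and T14. ITGA1 is at 34.2 to 50.1 in RNF4 libraries with Dox, and UCHL1 and AMOT are low in T13 (0.331 and 3.02) as well as in the libraries labelled RING mutant.

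The comparison of RNF4 with Dox against RING mutant with Dox would ask what depends on the catalytic activity of RNF4, if every library expressed its construct. RNF4 was near its level without Dox in T3 and T14, so the comparison cannot isolate that activity. The groups also carry different constructs, so a difference between the cells that hold them cannot be told apart from an effect of that activity. ITGA1 stood at 39.9 ± 8.82 CPM (SD, n = 3) with RNF4 and 70.5 ± 8.82 CPM in the libraries labelled RING mutant. PRRX1, a mesenchymal transcription factor, stood at 54.4 ± 0.488 against 92.3 ± 9.85 CPM, and WNT7B at 1.95 ± 0.286 against 4.17 ± 0.769 CPM. In the other direction UCHL1, a deubiquitinase, averaged 7.54 ± 10.3 CPM with RNF4 and 0.170 ± 0.194 CPM in the mutant libraries, and CA2, a carbonic anhydrase, 11.5 ± 16.8 against 0.252 ± 0.389 CPM. These higher means came from T2 above all and from T5, with UCHL1 at 19.4 CPM in T2 and 2.91 CPM in T5. Without T2 the log2 change fell from 5.32 to 3.11 for UCHL1 and from 5.35 to 2.72 for CA2. In T13 UCHL1 was at 0.331 CPM and CA2 at 0.372 CPM, against 0.394 and 0.700 CPM in T6.

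Fitted log2 values among genes lower with RNF4 were -0.76 ± 0.17 (SE) for PRRX1, -0.82 ± 0.21 for ITGA1, -0.80 ± 0.23 for TNFRSF19 (a TNF receptor family member), -0.65 ± 0.19 for SYTL5 and -1.10 ± 0.32 for WNT7B. Among higher genes HES4, a target of Notch signalling, had 1.84 ± 0.48, and the non-coding AL035425.3 (chromosome X, 108719949 to 108724944) had 6.85 ± 1.55. Both were uneven with RNF4: AL035425.3 had 55.8, 15.4 and 0.620 CPM in T2, T5 and T13 against 0.437 in T6, and HES4 had 19.4, 8.65 and 4.96 against 4.02 in T6. ENSG00000273190.1 had 1.85 ± 0.47, and neither it nor ENSG00000241732.1 is in GENCODE 29. Counts were few for several. ENSG00000241732.1 had 62 counts against 2 (ratio 26.4, 95% interval 6.999 to 223), PRSS30P 65 against 1 (55.3, 9.58 to 2217) and ZBED10P 95 against 1 (80.8, 14.2 to 3225). RIMS4 and LINC01515 had 0 counts in the mutant libraries and were at least 15.9-fold and at least 25.8-fold higher with RNF4. Most of these counts came from T2, with 48 of 65 for PRSS30P, 77 of 95 for ZBED10P, 37 of 56 for RIMS4, 82 of 91 for LINC01515 and 36 of 62 for ENSG00000241732.1. The authors' list for this comparison holds 8 genes, all higher with RNF4: AL035425.3, PRSS30P, RIMS4, UCHL1, LINC01515, RADX, ZBED10P and CA2. RADX, a DNA-binding protein of replication forks, had 4.88 ± 1.45 (36.5, 4.08 and 0.289 CPM in T2, T5 and T13, and 0.700 in T6), UCHL1 5.32 ± 1.48 and CA2 5.35 ± 1.58. RNF4 itself had 0.90 ± 0.77, which became 2.91 without T6.

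edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes here (smallest adjusted p 0.99988). At an unadjusted p under 0.05 there were 251 genes, 187 higher and 64 lower. DESeq2's Wald test and limma voom called 0, and edgeR's likelihood ratio test called 3 (AL035425.3, PRSS30P and ENSG00000241732.1). Without a low-count filter the quasi-likelihood test called 38, all higher. Groups did not overlap for 927 genes, 4.98% against the 10% of exchangeable libraries.

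6 lists passed camera's preset test, 4 of them up. The hypoxia list rose by a mean log2 difference of 0.38 with 28 of 29 members above 0 (camera adjusted p = 2.03e-11, adjusted p = 0.577 with an estimated correlation). ADM had 0.83 ± 0.27 and LOX, a collagen crosslinking enzyme, 1.44 ± 0.52. The ATF4 list rose by 0.26 with 26 of 31 members above 0 (camera adjusted p = 2.69e-05, adjusted p = 0.577 with an estimated correlation), with 1.14 ± 0.49 for asparagine synthetase (ASNS) and 0.35 ± 0.17 for VLDLR. ASNS rested on T2, with 148, 58.2 and 40.9 CPM in T2, T5 and T13 against 41.5, 41.0 and 29.3 in T3, T6 and T14, and was 0.41 without T2. ADM was 0.53 without T5. The hypoxia call held with each library left out, and the ATF4 call was lost without T14 (mean 0.20) or T5 (0.20). Ribosomal protein genes rose by 0.31 with 47 of 47 above 0 (camera adjusted p = 0.00208, adjusted p = 0.955 with an estimated correlation), with RPL3 at 0.33 ± 0.33 and RPL5 at 0.76 ± 0.80 (0.18 and -0.25 without T2). Their mean turned to -0.068 without T2, in which ribosomal protein genes took 11.1% of counts, and the call was lost without T14 (0.16). Heat shock genes rose by 0.17 with 18 of 22 above 0 (camera adjusted p = 0.0450, adjusted p = 0.955 with an estimated correlation), with DNAJB1 at 0.49 ± 0.26 and HSPA4L at 0.55 ± 0.31 (0.32 without T14 and 0.30 without T2). That call was lost without T6 (0.13), T14 (0.11) or T5 (0.17).

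Markers listed for host leukocytes and macrophages fell by a mean of -0.22 with 14 of 17 members below 0 (camera adjusted p = 0.0215, adjusted p = 0.955 with an estimated correlation). Whether their reads come from mouse or tumour cells was not tested. CD74, the invariant chain of antigen presentation, had -0.57 ± 0.21, and CYBB of the phagocyte oxidase -1.26 ± 0.57 (-0.41 without T14). The mean turned to 0.17 without T14, the library with the most of this signal, and the call was lost without T2 (-0.17) or T5 (-0.029). Interferon response genes fell by -0.10 with 25 of 35 below 0 (camera adjusted p = 0.0254, adjusted p = 0.577 with an estimated correlation), with RSAD2 at -1.13 ± 0.48 (-0.74 without T6) and XAF1 at -0.67 ± 0.30. That call was lost without T3 (-0.066), T6 (-0.066), T2 (-0.11), T5 (-0.089) or T13 (-0.10). Notch targets were not called as a list (mean 0.42, camera adjusted p = 0.0809). Their member HES4 passed adjusted over the list alone, 1 gene of 11, and HEY1 had 2.01 ± 0.78. HEY1 rested on T2 and HES4 did in part: HEY1 had 68.3, 14.2 and 6.41 CPM in T2, T5 and T13 against 5.93, 8.13 and 8.01 in T3, T6 and T14, and the values without T2 were 0.48 for HEY1 and 1.15 for HES4. Without T5 only 2 lists were called (ribosomal proteins and hypoxia), and 12 were called without T3 or without T13.

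**Figure D3:**
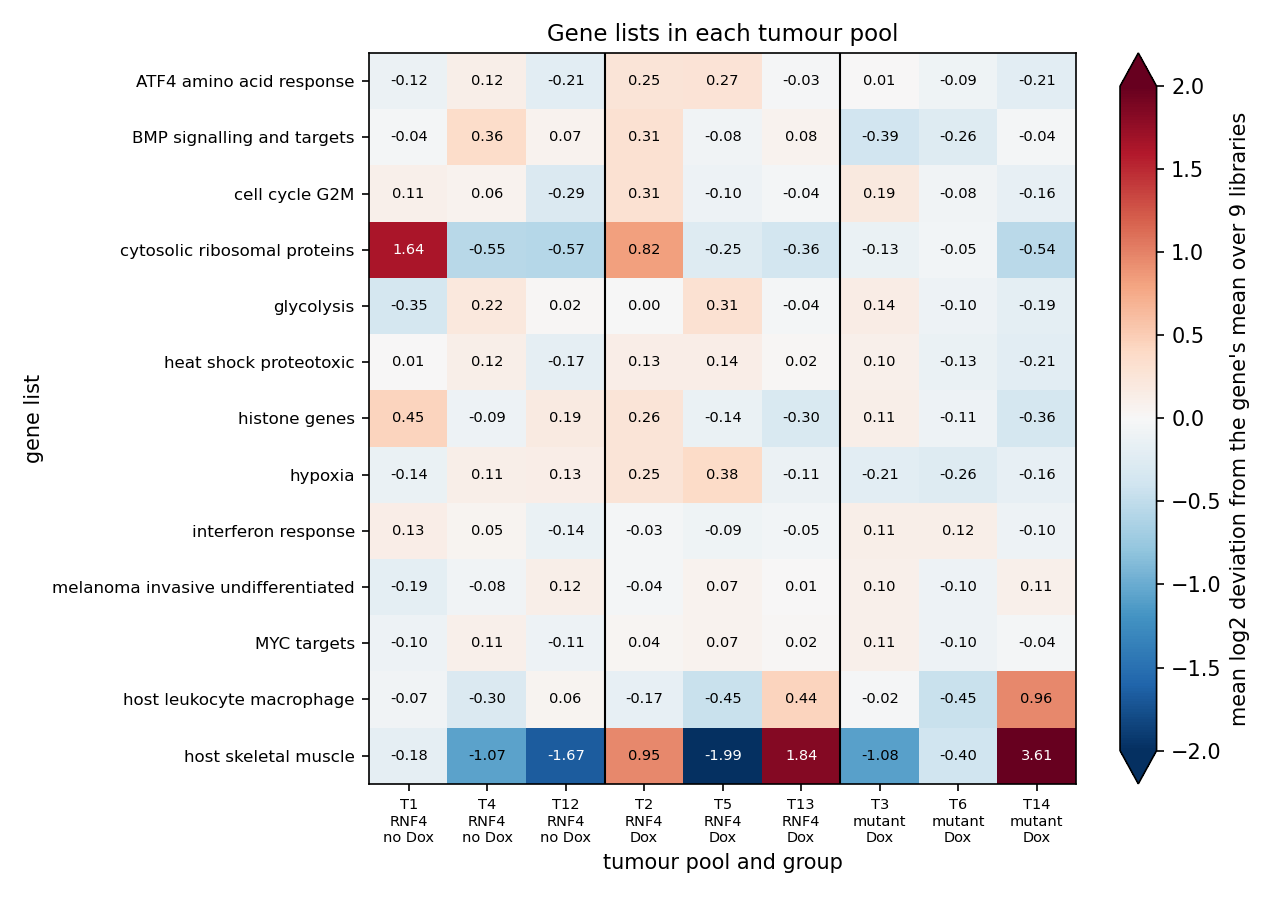
Mean log2 deviation from each gene's mean over the 9 libraries, for the 13 gene lists called in any comparison (vertical axis) in each tumour pool (horizontal axis, grouped by construct and Dox); numbers give the value and the colour scale stops at 2 either way. Ribosomal protein genes stand at 1.64 in T1 and 0.82 in T2, and skeletal muscle markers at 3.61 in T14.

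The comparison of RING mutant with Dox against RNF4 without Dox would ask what Dox and the inactive protein do, if every mutant library expressed its construct. RNF4 was near its level without Dox in T3 and T14, and the groups also carry different constructs. The comparison therefore cannot isolate Dox or the inactive protein. KCNAB1, a potassium channel subunit, averaged 32.3 ± 26.5 CPM (SD, n = 3) in the libraries labelled RING mutant and 4.75 ± 0.823 CPM without Dox, with 58.5 in T3, 33.0 in T6 and 5.57 in T14. It was also above the mean without Dox with RNF4 and Dox, at 26.9, 9.86 and 15.1 CPM in T2, T5 and T13. The anthrax toxin receptor ANTXR2 stood at 163 ± 47.6 against 88.0 ± 8.44 CPM. UCHL1 stood at 0.170 ± 0.194 against 9.53 ± 7.40 CPM, and the neurofilament gene NEFM at 0.365 ± 0.126 against 2.14 ± 1.38 CPM. AMOT, a regulator of Hippo signalling, and IRS4, an adaptor of insulin signalling, stood at 2.51 ± 1.56 and 0.175 ± 0.303 CPM against 44.8 ± 50.7 and 21.8 ± 27.9 CPM.

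Fitted log2 values were 2.76 ± 0.71 (SE) for KCNAB1 (chromosome 3, 156037701 to 156539138) and 0.89 ± 0.25 for ANTXR2. TYRP1, an enzyme of melanin synthesis, had 3.51 ± 0.99 and rested on T14, at 8.13 CPM against 0.612 and 0.770 in T6 and T3. The hair keratin gene KRT71 had 733 counts against 3 (ratio 304, 95% interval 103 to 1475), and 40.2 CPM in T14 against 1.19 and 0.262 in T3 and T6. T14 also stood high on host lists, with mean log2 deviations of 3.61 for skeletal muscle and 1.69 for keratinocyte markers (2.77 in T13). Whether the TYRP1 and KRT71 reads in T14 came from mouse or tumour cells was not tested. UNC5C-AS1 had 60 counts against 3 (24.8, 8.10 to 124), with 0 in T14. RNF4 had 2.38 ± 0.81, which became 0.36 without T6.

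Among lower genes the values were -5.66 ± 1.49 for UCHL1 (chromosome 4, 41256413 to 41268455), -2.54 ± 0.55 for NEFM, -7.06 ± 1.56 for AL035425.3, -5.46 ± 1.59 for CA2, -4.14 ± 1.103 for AMOT and -6.75 ± 1.88 for IRS4. AMOT (112774503 to 112840815) and IRS4 (108732482 to 108736409) lie on chromosome X, as does AL035425.3. Without Dox, T4 was far above T1 and T12 for AMOT (103, 14.8 and 16.2 CPM), IRS4 (53.9, 4.10 and 7.27 CPM) and AL035425.3 (53.4, 16.6 and 12.7 CPM). RIMS4 was at least 73.0-fold lower, with 0 counts against 272. ZBED10P had 1 count against 249 (200 times fewer, 95% interval 35.6 to 7949), PRSS30P 1 against 76 (61.2, 10.7 to 2448) and ENSG00000241732.1 2 against 62 (24.96, 6.62 to 211). The authors' lists hold 3 higher genes (KCNAB1, KRT71 and UNC5C-AS1) and 16 lower ones, among them RIMS4, AL035425.3, ZBED10P, PRSS30P, UCHL1, AMOT, IRS4 and CA2. All 19 had the authors' sign in the edgeR fit.

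edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes (smallest adjusted p 0.99996). At an unadjusted p under 0.05 there were 325, 68 higher and 257 lower. DESeq2's Wald test called 2, both lower (RIMS4 and AL035425.3). edgeR's likelihood ratio test called 5, all lower (RIMS4, AL035425.3, PRSS30P, ENSG00000241732.1 and INA), limma voom called 0, and the quasi-likelihood test without a low-count filter called 109. INA and FLT4, the single gene called with T1 and T2 left out, were named after their values were seen. Groups did not overlap for 704 genes, 3.78% against the 10% of exchangeable libraries.

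6 lists passed camera's preset test. Skeletal muscle markers rose by a mean log2 difference of 1.68 with 16 of 16 members above 0 (camera adjusted p = 7.39e-09, adjusted p = 0.873 with an estimated correlation), and T14 stood at 3.61 against -1.08 in T3 and -0.40 in T6. The call was lost without T14 (mean 0.24). MYH2 and MYH1 had 3.29 ± 1.11 and 3.48 ± 1.23, and 0.80 and 0.23 without T14. Leukocyte markers rose by 0.27 with 13 of 17 above 0 (camera adjusted p = 0.00845, adjusted p = 0.873 with an estimated correlation), again highest in T14, and their mean turned to -0.13 without it, while the call was also lost without T4 (0.17). CYBB and CSF1R had 0.95 ± 0.57 and 0.63 ± 0.51, and 0.11 and -0.089 without T14. The invasive melanoma list was called up with a mean log2 difference of 0.08 and 18 of 29 members above 0 (camera adjusted p = 0.00845, adjusted p = 0.873 with an estimated correlation). Its median fitted change was 0.10 whereas the mean fitted change was -0.0001, and its members S100A2 and F2RL1 had -1.47 ± 0.66 and 0.35 ± 0.19, with 0.10 for S100A2 without T1 and 0.22 for F2RL1 without T3. That call was lost without T1 (0.022) or T3 (0.049).

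Ribosomal protein genes fell by a mean of -0.41 with 47 of 47 below 0 (camera adjusted p = 0.000137, adjusted p = 0.960 with an estimated correlation), with RPL27 at -1.82 ± 1.01 and RPS14 at -1.58 ± 0.94. That call turned on T1, in which these genes took 17.4% of counts: without T1 the mean was 0.33, called in the other direction (camera adjusted p = 3.24e-06). It was lost without T14 (-0.26). The hypoxia list fell by -0.24 with 27 of 29 below 0 (camera adjusted p = 0.000370, adjusted p = 0.873 with an estimated correlation), with LOX at -1.11 ± 0.52 and EGLN3, an oxygen-sensing prolyl hydroxylase, at -0.69 ± 0.37 (-0.45 without T3), and the call was lost without T4 (-0.21) or T12 (-0.20). BMP signalling genes fell by -0.36 with 19 of 30 below 0 (camera adjusted p = 0.0396, adjusted p = 0.873 with an estimated correlation), with BMP7 at -2.24 ± 0.71 and ID2 at -0.84 ± 0.32, and the call was lost without T4 (-0.24) or T12 (-0.41). The Notch list was not called (mean -0.52, camera adjusted p = 0.0525). HES4 at -1.98 ± 0.48 passed adjusted over the list alone, 1 gene of 11, and HEY1 had -1.89 ± 0.77. Between 7 and 12 lists were called when single libraries were left out, with 12 without T3 or T14, 11 without T1 or T4 and 10 without T6.

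Genes tied to RNF4 or melanoma in earlier work are given as values. In RNF4 with Dox against RNF4 without Dox, log2 changes were 0.21 ± 0.18 (SE) for RGMB, -0.22 ± 0.42 for BMP6, -0.45 ± 0.26 for ID1, 0.10 ± 0.22 for MYC, -0.05 ± 0.23 for CTNNB1, 0.13 ± 0.29 for JUN and 0.06 ± 0.33 for MITF. Against the RING mutant they were 0.08 ± 0.18, 0.60 ± 0.44, -0.38 ± 0.26, 0.45 ± 0.22, -0.02 ± 0.23, 0.36 ± 0.29 and 0.21 ± 0.33 in that order. For RING mutant with Dox against RNF4 without Dox they were 0.12 ± 0.18, -0.82 ± 0.44, -0.07 ± 0.26, -0.35 ± 0.22, -0.03 ± 0.23, -0.23 ± 0.29 and -0.15 ± 0.33. None passed an adjusted p of 0.05 in the edgeR fit, and the intervals leave room for changes of the size of these errors. With single libraries left out several changed sign or size, such as BMP6 against the RING mutant, which was 0.09 without T2.

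A test of any difference among the 3 groups by edgeR's quasi-likelihood test called 0 genes (205 at an unadjusted p under 0.05, smallest unadjusted p in that edgeR test 0.00119), and DESeq2's likelihood ratio test called 2, RIMS4 and UNC5C-AS1. Fold changes of RNF4 with Dox and of RING mutant with Dox, both against RNF4 without Dox, correlated across 18618 genes with Pearson r = 0.553. Simulated unchanged groups with shared controls gave r = 0.498 on average (range 0.475 to 0.518 over 20 simulations), and genes are not independent replicates. The covariance was 0.113 against 0.132 in the simulations (range 0.124 to 0.140), and 66.9% of genes had the same sign against 66.5% (65.8% to 67.1%). The simulated libraries were drawn independently and hold no effects shared within runs of column numbers, whereas deviations from group means correlated at 0.675 for T1 and T2, 0.479 for T4 and T5 and 0.438 for T12 and T13. The simulation is therefore not a fitting null for these data, and no shared response is drawn from these values.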

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

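The tests of GC content and transcript length in T1 and T2, of GC content and length for X-linked genes, and of unadjusted p among 3 groups were set before their results were seen. The camera tests of the gene lists and the leaving out of single libraries were fixed before the data were examined. All other tests in this part were chosen after.

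RNF4 with Dox and RING mutant with Dox, each seen against RNF4 without Dox, differed in 6 gene lists by a test of their difference, and 2 of the genes the report names moved in opposite directions. By camera at the preset correlation the mean log2 differences were 0.38 for hypoxia, 0.26 for the ATF4 amino acid response, 0.31 for ribosomal proteins, 0.17 for heat shock genes, -0.22 for leukocyte markers and -0.10 for interferon response genes. None of the 6 passed camera with an estimated correlation, where the smallest adjusted p was 0.577. With single libraries left out only the hypoxia list kept its call each time: the ribosomal protein mean turned to -0.068 without T2, the leukocyte mean to 0.17 without T14, and the other 3 calls were lost at least once. ENSG00000273190.1 (log2 difference 1.85) and PRRX1 (-0.76) lay above the mean without Dox in every library of 1 group and below it in every library of the other. Neither difference passed edgeR's adjusted p, and the opposite movement itself was not tested. Both genes were named for a small unadjusted p between these same groups, a choice that favours such a pattern. How many of all tested genes show it was not counted, so it lends no support of its own. GADD45B, outside the report and named after its values were seen, had the same pattern. It had 24.4, 34.6 and 26.9 CPM in T2, T5 and T13 and 18.1, 20.6 and 16.9 CPM in T3, T6 and T14.

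RNF4 was near its level without Dox in T3 and T14, 2 of the 3 libraries labelled RING mutant. An exchange of labels with libraries without Dox needs a raised library among those, and the highest of them reached only 0.137 of the lowest library of RNF4 with Dox. A wrong label on T3 and T14 stays open. Of 48 genes very low in T6, 97.9% in T3 and 85.4% in T14 lay below every library without Dox, against 18.1% and 19.1% of all genes, but the RNF4 libraries with Dox gave 2.08% in T2, 66.7% in T5 and 83.3% in T13, so this value does not decide. A construct that was not induced or was lost also stays open: over 2 genes raised in every RNF4 library with Dox and in T6 (UNC5C and UNC5C-AS1), the median ratio to the mean without Dox was 0.142 in T14 and 26.7 in T3, and different activity of the mutant was not tested. These 2 genes overlap, so they stand for 1 locus, and UNC5C-AS1 had only 3 counts without Dox. UNC5C alone was at 8.51 times its mean without Dox in T3 and at 0.285 times in T14.

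T1 and T2 stood apart from the other 7 libraries although they belong to different groups, and the design names no biological difference that they share, so none of that kind was tested. Their deviations fell with GC content (Spearman rho across genes -0.353 in T1 and -0.414 in T2) and with transcript length (-0.404 and -0.248), while GC content gave 0.214 to 0.312 in T4, T5, T12, T13 and T14 with -0.0718 in T3 and -0.0352 in T6, and length 0.124 to 0.404 in T3, T4, T5, T6 and T12 with -0.0586 in T13 and -0.0551 in T14. Since values are taken from the mean of all libraries, trends in T1 and T2 in part produce the opposite elsewhere. More host stroma in these 2 libraries was not seen in the fibroblast, endothelium and leukocyte lists, which averaged -0.312 in T1 and -0.298 in T2 on the log2 scale. In T1 and T2 keratinocyte markers stood at -1.51 and -1.01, adipocyte markers at -0.063 and -0.0089, and skeletal muscle markers at -0.18 and 0.95. Mouse and human reads were not told apart, so these values limit stroma only as far as the lists reflect it. A bias in library preparation that acts through GC content and length may be part of the difference, but these values do not say which libraries carry it.

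Genes lower in the libraries labelled RING mutant than without Dox (unadjusted p under 0.05) were X-linked more often than other tested genes, 24 of 250 (9.60%) against 560 of 17912 (3.13%), odds ratio 3.29 (95% interval 2.05 to 5.07, Fisher's exact test p = 1.92e-06). Fisher's test takes genes as independent, whereas genes of the same libraries move together, so its p values and interval overstate the evidence. In this comparison no gene passed edgeR's adjusted p. GC content and length bias is argued against, since the odds ratio was 3.16 (Fisher's exact test p = 2.28e-06) with both trends removed. Loss of an X chromosome copy, in all or part of the cells, stays open. All 584 tested X-linked genes had a median log2 change of -0.133 (95% interval -0.160 to -0.110), against -0.0379 for other genes. The 24, chosen as low, had a median of -3.11. The test asked for a median below -1.56, a bound set from the 24. Loss of a copy need not reach that bound, so the test cannot decide. Loss of segments stays open as well. The 46 nearest tested genes on either side of the 24, with 4 of the 24 among them, had a median of -0.248 (95% interval -0.620 to -0.179). This lies below the median of all tested X-linked genes and above the same bound, which loss of a copy of a segment need not reach. Losses of single genes were not tested. A different cell population in the RING mutant line cannot be told apart either: the median ratio of the 24 genes to the mean without Dox was at most 0.117 in T3, T6 and T14, for which they were chosen as low, and it was 1.42, 0.438 and 0.115 in T2, T5 and T13 and 0.871, 1.68 and 0.389 in T1, T4 and T12.

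With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Since edgeR's quasi-likelihood test called 0 genes in each real split, every split gives as many (10, 10 and 10 of 10, and 100 of 100 drawn splits of the 9 libraries into 3 groups), which says nothing about chance. The highest other split called 0 genes in each comparison and 2083 among the 3 groups. At an unadjusted p under 0.05 the real splits gave 111, 251 and 325 genes and the highest others 5320, 1244 and 2880. Among the 3 groups the real split gave 205, the highest other 5788, and 85 of the 100 gave as many, so chance is not excluded.

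The splits with many genes point to a structure of the samples: the 5 of the 100 that called any gene all kept T1, T2 and T3 together. In all, 6 drawn splits kept these together, and the lowest of them called 0 genes. Most splits join libraries of a run of column numbers (T1 to T3, T4 to T6, T12 to T14), which the real ones never do, so the comparison above is uneven. Among the 4 splits per comparison that part the runs as the real one does, the others gave 95 to 229, 127 to 221 and 247 to 894 genes at an unadjusted p under 0.05, beside 111, 251 and 325. Among the 11 such splits of the 9 libraries that were drawn, 7 gave as many as the real one (205, others 82 to 332). With 4 splits no share can be under 0.05, and the labels do not say what the runs stand for.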

How the results depend on the processing

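The likelihood ratio test, limma voom, the libraries left out in pairs, the block of tumour number runs, and the GC content and length offsets were chosen after seeing the data. So was the use of the 2 filters for the RNF4 value, while those filters were planned for the other results. No paired analysis was possible because the numbers in the sample titles occur in no count column. Samples of equal number could thus not be matched to columns, and no block on those numbers was run. Runs of column numbers (T1 to T3, T4 to T6, T12 to T14) were used as a block instead: edgeR's quasi-likelihood test called 0 genes in each comparison (180, 391 and 403 at an unadjusted p under 0.05), with 9, 8 and 6 gene lists. These are not all the lists of the main fit, since 1 of its list calls was lost. Where T3 and T14 are left out, T6 is alone and is assumed to vary like the other groups. Unless a cause is named, the cause was not tested.

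Counts of genes in RNF4 with Dox against RNF4 without Dox were 3 with no low-count filter, 3 by DESeq2 and 1 by the likelihood ratio test. Against RING mutant with Dox they were 38 with no filter and 3 by the likelihood ratio test. In RING mutant with Dox against RNF4 without Dox they were 109 with no filter, 2 by DESeq2, 5 by the likelihood ratio test and 1 with T1 and T2 left out (FLT4). Among the 3 groups they were 87 with no filter and 2 by DESeq2's likelihood ratio test. Without the filter 38388 genes entered and the prior degrees of freedom of the fit went from 3.72 to 41.3, and these were not varied apart. With each library left out in turn, edgeR's quasi-likelihood test called 0 to 0 genes in the 3 comparisons (76 to 400, 120 to 415 and 266 to 506 at an unadjusted p under 0.05) and 0 to 1 among the 3 groups (1 without T6).

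RNF4 log2 fold change, RNF4 with Dox against RNF4 without Dox, was 3.27 with no filter (edgeR adjusted p 0.000485, with 0.0878 to 1 under the other alternatives), 3.38 with runs as a block and 3.13 to 3.44 with a library left out. RNF4 log2 fold change, RNF4 with Dox against RING mutant with Dox, was -0.43 with T3 and T14 left out, where T6 with 559 CPM stands for its label. It was 1.65 with runs as a block (unadjusted edgeR p 0.0445, edgeR adjusted p 0.9999), 0.35 with T13 and T14 left out, and 0.41 (without T3) to 2.91 (without T6, edgeR adjusted p 0.162, the lowest of its alternatives). RNF4 log2 fold change, RING mutant with Dox against RNF4 without Dox, was 2.40 with no filter (edgeR adjusted p 0.00772, with 0.141 to 1 under the other alternatives). It was 3.71 with T3 and T14 left out (edgeR adjusted p 0.141, T6 alone), 1.73 with runs as a block, 2.85 with T13 and T14 left out, and 0.36 (without T6) to 2.86 (without T3). The correlation of fold changes of the 2 comparisons against RNF4 without Dox was 0.592 with the stricter filter, and 0.671 to 0.753 with a library without Dox left out, where 2 shared controls stand in place of 3.

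Counts of gene lists in RNF4 with Dox against RNF4 without Dox were 0 with an estimated correlation, 4 with T3 and T14 left out, and 7 to 14 (without T4) with a library left out. Against RING mutant with Dox they were 0 with an estimated correlation, 10 with T1 and T2 left out, 10 with T13 and T14 left out, and 2 (without T5) to 12 (without T3 or T13). In RING mutant with Dox against RNF4 without Dox they were 0 with an estimated correlation, 12 with the host score as covariate, 10 with T1 and T2 left out, 12 with T13 and T14 left out, and 7 to 12. List values below are mean log2 differences. The 20 list results gave 300 values: 200 kept direction and call, 87 lost the call and 13 reversed. The estimated correlation ended 20 calls. With single libraries left out, the ATF4 list against RNF4 without Dox and the hypoxia list against RING mutant with Dox kept their calls each time, and the other 18 calls were lost or reversed at least once.

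The 104 gene results gave 1964 values: 1868 kept direction and side of the threshold, 43 came to pass it and 53 reversed, while 82 results never reversed. With T1 and T2 left out, RNF4 with Dox against RNF4 without Dox gave 0.32 for CKS2, -0.0481 for SLC16A1, 0.0034 for H4C3 and -0.10 for MYC, and against RING mutant with Dox RPL5 gave -0.27 and the ribosomal protein list -0.082. In RING mutant with Dox against RNF4 without Dox it gave 0.62 for RPL27, 0.54 for RPS14, 0.11 for S100A2, 0.22 for ID1 and 0.34 for the ribosomal protein list. These ribosomal reversals follow from leaving out the 2 libraries with 17.4% and 11.1% of counts in those genes.

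With T13 and T14 left out, BMP6 gave 0.004 in RNF4 with Dox against RNF4 without Dox, RGMB -0.044 against RING mutant with Dox, and in RING mutant with Dox against RNF4 without Dox CSF1R gave -0.070, MITF 0.0023 and the leukocyte list -0.11. With T3 and T14 left out, CTNNB1 gave 0.22 and the leukocyte list 0.29 in RNF4 with Dox against RING mutant with Dox. In RING mutant with Dox against RNF4 without Dox it gave -0.12 for CYBB, -0.31 for CSF1R, -0.26 for the leukocyte list and -0.0475 for the invasive melanoma list. With limma voom, CKS2 gave 0.22 in RNF4 with Dox against RNF4 without Dox, RPL5 -0.14 and CTNNB1 0.16 against RING mutant with Dox, and in RING mutant with Dox against RNF4 without Dox RPL27 gave 0.33, RPS14 0.25, CYBB -0.017, CSF1R -0.33 and ID1 0.10. With GC content and length offsets ID1 gave 0.015 in RING mutant with Dox against RNF4 without Dox.

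With a library left out in RNF4 with Dox against RNF4 without Dox, values ran from -1.71 to 1.27 for CKS2, -0.026 to 0.40 for PFKM, -0.0086 to 0.24 for SLC16A1, -0.73 to 0.023 for BMP6, -0.027 to 0.33 for MYC, -0.16 to 0.077 for CTNNB1, -0.092 to 0.42 for JUN and -0.26 to 0.39 for MITF. Its G2/M list ran from -0.033 to 0.18 and its glycolysis list from -0.021 to 0.26. Against RING mutant with Dox, RPL5 ran from -0.25 to 1.09, RGMB from -0.038 to 0.20, CTNNB1 from -0.13 to 0.10, MITF from -0.11 to 0.43, the ribosomal protein list from -0.068 to 0.53 and the leukocyte list from -0.53 to 0.17. In RING mutant with Dox against RNF4 without Dox, RPL27 ran from -2.32 to 0.61, RPS14 from -2.07 to 0.54, CSF1R from -0.089 to 0.94, S100A2 from -1.88 to 0.10, ID1 from -0.25 to 0.22, CTNNB1 from -0.16 to 0.094, JUN from -0.45 to 0.057 and MITF from -0.29 to 0.18. Its ribosomal protein list ran from -0.78 to 0.33 and its leukocyte list from -0.13 to 0.57.

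RLE factors moved the median of all genes by 0.00325, -0.00832 and 0.0116 on the log2 scale in the 3 comparisons. They ended 1 list call, leaving 5 lists in place of 6 in RNF4 with Dox against RING mutant with Dox. The host score as covariate ended 4 list calls. Depth limits the genes with few counts, whose counting intervals are given with them.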

Other observations

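Several host cell markers were higher in T12, T13 and T14, which belong to 3 different groups, than in the other 6 libraries, a pattern seen after the data were examined. Keratinocyte markers averaged 1.37, 2.77 and 1.69 (log2 deviation from the mean of 9 libraries) in T12, T13 and T14, against -1.51 to -0.07 in the other 6 libraries. Fibroblast markers averaged 0.22, 0.81 and 0.96 in T12, T13 and T14, against -0.68 to -0.04 in the other 6. Endothelial markers averaged 0.58, 0.74 and 0.51, against -0.66 to 0.32. Other host lists broke the pattern in T12, with -1.67 for skeletal muscle and -0.27 for adipocyte markers. Mitochondrially encoded genes averaged 0.57, 0.56 and 0.89, with 0.49 in T1 and -0.82 to -0.02 in the other 5. Deviations from group means correlated between libraries of a run at 0.675 for T1 and T2, 0.0861 for T1 and T3, 0.157 for T2 and T3, 0.479 for T4 and T5, 0.000436 for T4 and T6, 0.249 for T5 and T6, 0.438 for T12 and T13, 0.398 for T12 and T14, and 0.569 for T13 and T14. The labels do not say what the runs stand for.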
